A study of Drosophila melanogaster and Drosophila pseudoobscura and Drosophila simulans with 70 samples.

How the data were processed

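Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was run on embryos of 5 Drosophila species. The targets were the Polycomb group proteins PH, PC and PHO, the DNA-binding protein DSP1 and the histone marks H3K27me3 and H3K4me3, with input DNA beside them. The series holds 70 samples in 39 groups. Of these, 64 have a profile over the genome, 4 have a list of peaks or domains, and 2 inputs of the lists have no file and were not used here.

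The deposited profiles give 1 score per library and 20 bp bin. The labels state no unit. Tested on the values, each score equals the negative log2 of the share of that library's mapped bins with a value at least as high, to within 1.05e-05 in all 64 columns. A score of 1 therefore marks the upper 50% of bins, and each further unit marks a 2-fold smaller share. Because ranks give each library nearly the same distribution apart from its zero bins, a change in the level of a whole library cannot be seen. A change at many bound sites shows only where it moves their rank against other bins. Read counts are not given, so the depth of each library is unknown and no counting interval can be put on a score. The share of bins with a score of 0 ran from 0.0941% to 64.4% between libraries. Mean scores over all bins therefore differed, from 1.19 to 1.44 in D. melanogaster. Per the labels, the authors aligned reads with Bowtie 0.12.2 and named the fly build dm3. The D. melanogaster profiles carry dm3 chromosome names and lengths, while the profiles of the other species are on their own chromosomes or scaffolds and no map between species was given. How the authors binned and scaled the reads is not stated.

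The deposited lists hold a score per PH peak, whose formula is not stated and which is 50 or higher, and a score per H3K27me3 domain, a whole number of at least 220 whose meaning is not stated. The labels name Bowtie and SICER without versions for them, and the peak names begin with MACS_peak. Peaks overlapping by 1 bp between both replicates were merged to regions, and domains likewise. The shared regions on chromosome arms with a profile were tested if at least 10 bins and 50% of their bins were mapped, which left 1377 regions.

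Values were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and R 4.3.3. The PHdel and WT libraries were compared by limma 3.58.1 on the mean score of each region, with a variance trend, 2 libraries per genotype and Benjamini-Hochberg adjustment at 0.05. The score is already a log scale, so it was tested without a further logarithm; log2 of the score plus 1 was run as an added alternative. No background scaling was applied, since ranks are already relative to the library. Differences of scores replaced ratios for the same reason. Tested on simulated data with 2 against 2 libraries, the PHO fit recovered 8.82%, 63.6% and 100% of planted changes of 1, 2 and 4 units, and the PC fit recovered 0%, 6.06% and 48.5%. The simulated noise was independent between regions, and the planted changes went in both directions. The measured regions moved together, so these rates may not hold for them. An exact permutation of 2 against 2 libraries cannot give a two-sided p below 0.333. Region groups (inside domains, on X) were tested with camera from limma at a preset correlation of 0.01 and at an estimated one.

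The overlap of PH regions with domains was compared with 1000 circular shifts along each chromosome arm, in a one-sided permutation test. Shared binding within a species was measured in 1000 bp windows with at least 50% of bins mapped. A window counted as enriched when its mean score over the libraries of a target was at least 5 and at least 1 above the mean input score. The minimum of 5 was set after the profiles had been seen. Intervals on shares are exact Clopper-Pearson intervals at 95%; they cover counting error only, and neighbouring windows are not independent. The genotype of the PHdel libraries was checked by searching 500 bp windows for runs of at least 25 with input scores below 0.6 in PHdel and more than 0.5 higher in WT, both PHdel inputs lying below both WT inputs. That criterion was settled after several forms had been tried on the data.

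D. simulans PH replicates 1 and 2 shared their zero bins almost bin by bin: 0.692% of bins were 0 in 1 of them, where independent libraries would give 45.9%. They were counted as 1 sample. The criterion for such near copies (a correlation over 20 bp bins above 0.95, more than 10% zero bins and far fewer mismatched zeros than by chance) was set after seeing the data. The D. melanogaster PHO pair of 4 to 12 h passed that correlation (0.9535) but had 0.889% and 1.23% zero bins. The criterion could therefore not judge this pair, which was used as 2 replicates.

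The regions named were fixed by a rule before the data were examined: for each contrast up to 10 regions that rose and 10 that fell past the threshold and moved the same way in every pair of libraries, and for the domains the 10 longest present in both lists. The 14 gene lists fixed with it were not used here, because the reference at hand held no gene positions for dm3; regions are named by dm3 coordinates. Comparisons of the same locus between species were not made for want of a map. Alternatives covered the region set, the region width, the filter, the input, the replicate block, each library left out, the window size, the enrichment threshold and the replicates taken alone.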

Results

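The series concerns how Polycomb proteins find their targets, how they cooperate there and how stable this is between Drosophila species. Polycomb group proteins keep developmental genes silent. PH (Polyhomeotic) and PC (Polycomb) are subunits of Polycomb repressive complex 1, PHO (Pleiohomeotic) is a DNA-binding member of the group, and DSP1 is an HMG-box DNA-binding protein. H3K27me3 is the histone mark of Polycomb-silenced chromatin, and H3K4me3 marks active promoters. Libraries from embryos of 4 to 12 h numbered 52 and covered D. melanogaster (mel), D. simulans (sim), D. yakuba (yak), D. pseudoobscura (pse) and D. virilis (vir). Another 12 came from D. melanogaster embryos of 16 to 18 h that were wild type (WT) or carried a deletion of ph (PHdel), with 2 libraries each for PC, PHO and input. Lists of PH peaks and H3K27me3 domains came from 2 WT samples each at 16 to 18 h. D. melanogaster and D. pseudoobscura had 2 libraries of each target at 4 to 12 h; D. simulans and D. yakuba had 1 of PC, DSP1, H3K27me3 and H3K4me3 and 2 of PHO; D. virilis had 1 of H3K27me3 and 2 inputs. The values are rank scores, so read depth is unknown. Mapped bins numbered 5778018 in D. melanogaster, 5358600 in D. simulans, 5640699 in D. yakuba, 5892125 in D. pseudoobscura and 7325323 in D. virilis.

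PH peaks of wild-type embryos lay largely inside H3K27me3 domains. The 2 PH lists held 1776 and 1866 peaks and shared 1519 regions, of which 1393 lay on chromosome arms with a profile. Of these, 1140 (81.8%) overlapped 1 of the 539 domains present in both domain lists. Shifted along the arms, 18.7% of the regions did so on average, 260.6 ± 31.1 regions (SD, 1000 shifts), with 453 as the highest count. The one-sided permutation p was 0.001, the smallest that these shifts can give. The shared domains covered 21.6 Mb with a median length of 21999 bp. The lists of the replicates overlapped by 87.8% and 81.9% for PH peaks, and by 74.5% and 56.3% for H3K27me3 domains.

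The 10 longest domains differed widely in how many PH regions they held. The longest, 3L 18107501 to 18455999 (348 kb), held 10 and the next, 3R 6241501 to 6512999, held 19. The domain 3R 12588001 to 12813999 held 37, the highest number among them, and 3R 2648501 to 2893499 held 27. No shared PH region lay in 3L 13043001 to 13264999, and 4 lay in 3L 20519501 to 20746499. The other domains of this group were 2L 21762501 to 21981499 with 12 regions, 2L 11285001 to 11495999 with 14, 3R 17200001 to 17399999 with 23 and 3L 12530001 to 12729499 with 21. At 4 to 12 h, mean H3K27me3 scores across 3R 12588001 to 12813999 were 4.87 and 4.28 in the 2 libraries, against 1.78 and 1.63 across 3L 13043001 to 13264999. These are extremes, and the scores did not follow the number of PH regions throughout. The domain 3R 6241501 to 6512999, with 19 regions, had 1.86 and 1.79, while 3R 17200001 to 17399999, with 23, had 4.75 and 4.31. An annotation of genes in this build was not used here, so the genes in these domains are not named.

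The PH regions mapped in older embryos carried Polycomb chromatin at 4 to 12 h as well. Over the 1139 tested regions inside domains the mean H3K27me3 score was 3.56 ± 0.09 (SD, n = 2), against 1.13 ± 0.17 over the 238 tested regions outside. PHO scored 3.49 ± 0.06 inside and 2.08 ± 0.02 outside, and PC scored 2.36 ± 0.08 and 1.42 ± 0.27. PH itself scored 3.10 ± 1.67 inside and 1.52 ± 0.28 outside, the 2 PH libraries lying at 1.92 and 4.28 inside domains. H3K4me3 differed by less than its SD, at 1.37 ± 0.16 inside and 1.39 ± 0.22 outside. DSP1 was higher inside by 0.19, about as much as input with 0.18. Input scored 1.62 ± 0.15 inside and 1.44 ± 0.15 outside at this age, but the WT inputs of 16 to 18 h scored 1.59 ± 0.01 inside and 2.55 ± 0.02 outside, and the PHdel inputs 1.91 ± 0.00 and 2.22 ± 0.39.

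The PHdel libraries had little signal over 2 stretches, called the missing stretches below, where the WT libraries had more. The first, X 2007001 to 2029500 (22.5 kb), lies near the tip of the X chromosome, where the ph genes are. The stretches were found from the inputs, so the inputs cannot check them. On X the PC and PHO libraries check them only in part. That stretch holds a strong PC site (8.25 and 8.26 in WT at X 2015399 to 2020846), where lost binding would lower the scores too. In the PC and PHO libraries, the mean score on X ran from 0.54 to 0.77 in PHdel and from 3.48 to 4.54 in WT. Relative to the rest of X the mean was -0.28 ± 0.12 in PHdel and 2.77 ± 0.55 in WT (SD, n = 4). The PHdel scores thus lay only a little below those of the rest of X. The second, 3L 20501 to 42500 (22 kb) at the tip of 3L, scored 0.29 to 0.57 in the PC and PHO libraries of PHdel and 1.47 to 2.60 in those of WT. No PC or PHO library of PHdel overlapped one of WT in either stretch. The next run of windows low in PHdel had 11 windows against 31 for X and 39 for 3L. The longest run low in WT had 24, just under the minimum of 25. In all, more windows were low in WT (9160) than in PHdel (2699) by the same rule.

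**Figure D1:**
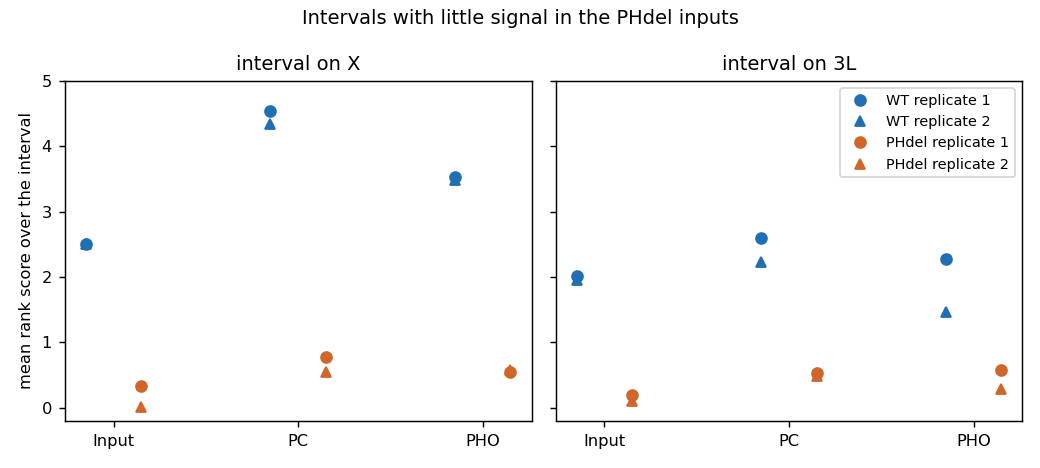
Mean rank score (vertical axis) over the stretches of X and 3L with little signal in the PHdel inputs, for input, PC and PHO libraries of 16 to 18 h embryos. Each point is 1 library. The inputs were used to find the stretches; of the others, the PHdel libraries sit between 0.54 and 0.77 on X and the WT libraries between 3.48 and 4.54.

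Whether PC binding at PH sites depends on PH was asked by comparing PC in PHdel and WT embryos, and the PC libraries did not settle it. Over the 1139 PH regions inside domains, median PC scores were 4.84 and 2.39 in the WT replicates and 2.44 and 2.24 in the PHdel replicates. WT replicate 1 stood far above the other 3 libraries there, while WT replicate 2 was within the range of scores of PHdel replicates 1 and 2. The median change inside domains was -1.16, with medians of the 4 library pairs from -2.43 to 0.06; outside domains it was 0.01. With the input in the model these medians were -1.51 and 0.39. Outside domains mean WT PC was 2.96 ± 0.03 and mean WT input 2.55 ± 0.02, against 3.88 ± 1.61 and 1.59 ± 0.01 inside. Regions outside thus had little PC above input to lose, so their small change does not show that a fall was confined to domains. Both PHdel libraries lay below both WT libraries in 430 of the 1139 regions (37.8%). Chance gives 16.7% for 1 region with 4 alike libraries, but WT replicate 1 stood high across regions. The regions also moved together (estimated correlation 0.741 in camera), so this share does not measure an excess over chance. On X, 133 of 197 regions inside domains (67.5%) had both PHdel libraries below both WT libraries. Each of the 4 library pairs had a median below 0 there, from -2.83 to -0.47. PC was lower elsewhere on X too: outside domains the median change of its 49 PH regions was -0.40 with all 4 pairs below 0, and in windows without peaks or domains the X minus autosome score was -0.55 and -0.54 in the PHdel PC libraries against -0.20 and -0.15 in WT. No region passed the limma test in either direction, 0 rose and 0 fell, and 63 of the 1377 regions had an unadjusted p under 0.05. The result turned on 1 library: 881 regions fell and 16 rose without WT replicate 2, while 1 fell and 0 rose without WT replicate 1. The regions inside domains were lower as a group by camera at the preset correlation (p = 5.24e-26), but not with an estimated correlation (p = 0.265).

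Scores of PHO at PH sites were lower in PHdel embryos in the regions inside domains, and 3 regions passed the test, all on X. Inside domains the median PHO scores were 2.96 and 3.34 in WT and 2.03 and 2.57 in PHdel. The median change was -0.78 and all 4 library pairs had a median below 0, from -1.23 to -0.39. Outside domains the median change was -0.13, with pairs from -0.36 to 0.08; with the input in the model the medians were -1.15 inside and 0.23 outside. Mean WT PHO was 2.87 ± 0.34 outside, near the WT input of 2.55 ± 0.02 there, against 3.27 ± 0.22 and 1.59 ± 0.01 inside. The small change outside therefore does not show that the fall was confined to domains. Both PHdel libraries lay below both WT libraries in 624 of 1139 regions inside domains (54.8%) and in 54 of 238 outside (22.7%). Chance gives 16.7% for 1 region, but regions of the same 4 libraries move together, so such shares do not measure an excess over chance. Regions inside domains had a median change of -0.67 on the autosomes and -1.25 on X, and on X 163 of 197 (82.7%) had both PHdel libraries below both WT libraries. Outside domains the median change was -0.01 on the autosomes and -0.62 on X, where 26 of 49 regions (53.1%) had both PHdel libraries below both WT libraries. Camera gave p = 8.15e-12 for the regions inside domains and p = 1.6e-12 for those on X at the preset correlation, and p = 0.206 and p = 0.124 with an estimated correlation.

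By limma, 3 of the 1377 regions fell, 0 rose, and 271 had an unadjusted p under 0.05. The region X 2015399 to 2020846 fell by 4.91 (SE 0.60, adjusted p = 0.00191), from a mean of 6.28 in WT to 1.37 in PHdel; it lies within the stretch of X missing from the PHdel inputs. X 7017932 to 7019484 fell by 3.28 (SE 0.59, adjusted p = 0.0409), from 4.86 to 1.58. X 8348467 to 8350471 fell by 3.25 (SE 0.59, adjusted p = 0.0409), from 4.82 to 1.57. In each of the 3 regions both PHdel libraries lay below both WT libraries. No region passed with the input in the model (0 fell, 358 at an unadjusted p under 0.05) or among autosomal regions alone (0 fell, 170). The same held with regions from either PH list (0 fell, 202) and without the regions in the missing stretches (0 fell, 269). In the last case the lowest adjusted p by limma was 0.0601 and the median change inside domains stayed at -0.78. By contrast, 82 fell among the higher-scoring peaks alone. With the replicate number as a block 384 fell and 18 rose, although only that number pairs the libraries. Leaving out single libraries gave 223 regions that fell and 39 that rose without WT replicate 1, 30 and 0 without WT replicate 2, and 21 and 1 without PHdel replicate 2.

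**Figure D2:**
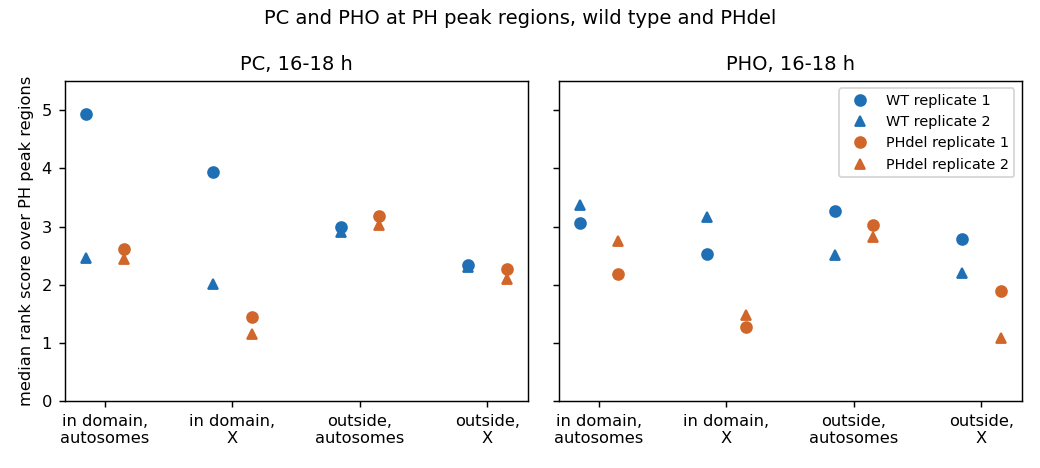
Median rank score (vertical axis) of PC and PHO over PH peak regions inside and outside H3K27me3 domains, on autosomes and on X, at 16 to 18 h. Each point is 1 library; inside domains the PC medians of WT replicate 1 lie above all others, and the PHO medians of both PHdel libraries lie below both WT libraries.

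The longest domains with PH regions followed the same lines. Averaged over the PH regions of each domain, PC was lower in PHdel by mean in each of the 9 domains, with changes from -1.32 to -0.72, but both PHdel libraries lay below both WT libraries in 2 of them. These were 2L 11285001 to 11495999, where the mean in PHdel was 2.28 ± 0.11 and the change -1.32, and 3R 6241501 to 6512999, with 3.82 ± 0.86 in WT and 2.64 ± 0.13 in PHdel (SD, n = 2). For PHO, both PHdel libraries lay below both WT libraries in 7 of the 9, and the change was below 0 in 8. The exception was 3R 12588001 to 12813999, the domain with 37 PH regions, where PHO scored 4.13 ± 0.08 in WT and 4.35 ± 0.42 in PHdel, a change of 0.21. Within that domain lies 3R 12726501 to 12738500 (12 kb), a run of 19 windows of 500 bp that were low in the WT inputs. Their mean input scores were 0.40 in WT and 1.48 in PHdel. Whether this run affects the PHO change of the domain was not tested. In 3R 17200001 to 17399999, PHO scored 3.46 ± 0.43 and 3.02 ± 0.53 and the libraries of the genotypes overlapped.

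How far Polycomb proteins and marks share their sites was compared between species within each genome at 4 to 12 h. In D. melanogaster 58.2% of the 376 windows enriched for PH were enriched for H3K27me3 too (55.7% and 55.6% with the replicates taken alone), and in D. simulans 66.3% of 457. With the near copies PH replicates 1 and 2 alone the D. simulans share was 68.1% of 357, and with PH replicate 3 alone 41.1% of 978. The share was 37.8% of 929 in D. yakuba (95% interval 34.7% to 41.0%) and 39.1% of 611 in D. pseudoobscura (31.7% and 35.5% in the replicates). The number of PH windows moved with single libraries in these species too, to 704 and 1520 in the D. yakuba replicates and 416 and 1365 in those of D. pseudoobscura. In the D. melanogaster replicates it was 167 and 1208, with odds ratios of 73.3 and 213. The near equal shares of these 2 replicates therefore do not measure their spread. Of all windows, 1.32% were enriched for H3K27me3 in D. melanogaster, 2.75% in D. simulans, 2.14% in D. yakuba and 2.38% in D. pseudoobscura. D. melanogaster lay above D. pseudoobscura in both replicates, while D. simulans with PH replicate 3 alone lay near D. yakuba and D. pseudoobscura. No test across species was run. The level depended on how windows were chosen: among the 1000 windows highest over input the shares were 39.1%, 20.3%, 21.0% and 10.7% in the same order, so that D. simulans no longer stood above D. yakuba. With no score minimum these species had 39.0% and 35.9%.

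Windows enriched for PHO included some with Polycomb chromatin, some with H3K4me3 and some with neither in each of the 4 species. PH, PC or H3K27me3 was enriched in 34.4% of the PHO windows in D. melanogaster, 53.7% in D. simulans, 61.8% in D. yakuba and 44.9% in D. pseudoobscura. Neither these nor H3K4me3 were enriched in 45.2%, 22.7%, 13.1% and 23.1%. No share over all windows was computed for these classes. PH was enriched in 29.0% of the 1021 PHO windows in D. melanogaster, 46.0% of 594 in D. simulans, 58.8% of 899 in D. yakuba and 37.4% of 1206 in D. pseudoobscura. PH covered 0.325%, 0.422%, 0.828% and 0.515% of all windows, and the odds ratios, 585, 497, 396 and 438, were in a different order from the shares. The replicates alone gave 12.9% and 42.7% in D. melanogaster, 38.9% (PH replicates 1 and 2) and 62.8% (PH replicate 3) in D. simulans, 52.1% and 63.9% in D. yakuba, and 22.9% and 55.6% in D. pseudoobscura, so that most differences between species lay within the spread of replicates. H3K4me3 was enriched in 20.4%, 25.4%, 32.5% and 33.4% of PHO windows in the same order. For this share the replicates of D. melanogaster (19.5% and 21.4%) lay apart from those of D. pseudoobscura (32.6% and 34.6%), but H3K4me3 covered more of all windows in D. pseudoobscura (2.17% and 3.20% against 1.08% and 1.02%). The odds ratios overlapped, at 26.3 and 32.3 in D. melanogaster and 28.5 and 16.2 in D. pseudoobscura. Among the 1000 windows highest over input the shares were 10.5%, 8.10%, 15.4% and 22.5%, and in 2 kb windows D. melanogaster had 9.29%. An exact permutation of 2 against 2 values cannot give a two-sided p below 0.333.

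PH and PC shared sites in all 4 species, while windows enriched for both histone marks were rare. PC was enriched in 53.7% of PH windows in D. melanogaster, 82.7% in D. simulans (86.6% and 47.3% with PH replicates 1 and 2 or PH replicate 3 alone), 73.0% in D. yakuba and 73.8% in D. pseudoobscura. In D. melanogaster the replicates alone gave 81.4% and 14.2%, with 167 and 1208 PH windows and 422 and 193 PC windows. PC windows numbered 206, 762, 1475 and 1069 in the same order. In D. melanogaster they were fewer than the 376 PH windows, which bounds the share. Taken the other way, PH was enriched in 98.1%, 49.6%, 46.0% and 42.2% of PC windows (32.2% and 89.1% in the D. melanogaster replicates). The odds ratios were 33497, 1338, 374 and 535. The lower share in D. melanogaster therefore does not measure less sharing. Among the 1000 windows highest over input, PC was enriched in 60.1%, 52.4%, 62.8% and 51.5% of PH windows, and the order of the species changed. H3K4me3 was enriched in 0.196%, 0.201%, 0.166% and 0.106% of H3K27me3 windows in these species, where it covered 0.865%, 1.99%, 1.89% and 2.55% of all windows. The share was 0.735% in D. melanogaster replicate 1 alone (odds ratio 0.675) and 0.456% in D. pseudoobscura replicate 2 alone. With no score minimum it was 0.726%, 9.12%, 5.94% and 4.08%, against 3.51%, 10.7%, 9.12% and 9.24% of all windows, so that in D. simulans the marks were then together nearly as often as in windows at large.

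**Figure D3:**
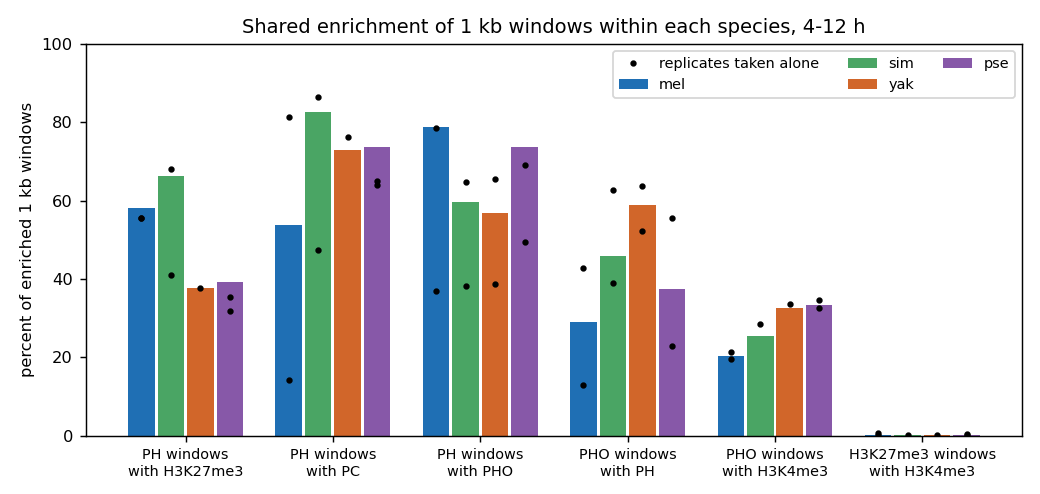
Percent of the 1 kb windows enriched for the first-named target that were enriched for the second as well (vertical axis), in 4 species at 4 to 12 h. Bars use the mean of all libraries and black points replicates taken alone, which for PH in sim are replicates 1 and 2 as 1 sample and replicate 3. PH windows had H3K27me3 in 58.2%, 66.3%, 37.8% and 39.1% of cases in mel, sim, yak and pse, and in 41.1% in sim with PH replicate 3 alone.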

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

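Of the 1519 PH regions found in both lists, 126 lie on sequence outside the profiles and therefore took part in no comparison. They stand out because they are signal in deposited data that the comparisons leave aside. Of the 539 H3K27me3 domains in both lists, 1 lies outside the profiles. No control list of peaks exists, so the number has no background value among peaks, and no biological explanation was tested.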

How the results depend on the processing

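Alternatives on log2 of the score plus 1, on the variance trend, on autosomes alone, on the missing stretches, on the score minimum, on the 1000 windows highest over input and on the D. simulans PH replicates (1 and 2 as 2 samples, 1 and 2 alone, 3 alone) were chosen after seeing the data; the others were planned. Without 1 library, the remaining sample of that genotype is assumed to vary like the others. PH regions lay in domains at 78.0% to 91.5% in all 5 alternatives, each with a permutation p of 0.001, the smallest these can give. Over the missing stretch on X, PHdel minus WT was -2.75 relative to the rest of X and -2.57 relative to 200 kb on either side, and -3.05 in the PC and PHO libraries alone, an alternative added after seeing the data.

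Of PC regions, 1 fell with 1 kb around the middle of the peak (1 rose) and 1 fell with log2 of the score plus 1; leaving out single libraries gave 0 to 881 that fell and 0 to 16 that rose. The median PC change inside domains ran from -2.37 to 0.03 over these, the last without WT replicate 1. Of PHO regions, 0 fell with the input in the model, with regions from either list, on autosomes alone and without the missing stretches. With a replicate block 384 fell and 18 rose, but only the replicate number pairs the libraries, and deviations within pairs correlated at 0.557 for PHO and 0.122 for PC, where the block gave 0 and 0 (42 at an unadjusted p under 0.05 by limma). With 1 kb around the middle 5 fell, and with the higher-scoring peaks alone 82 fell; without the filter 1 rose. Leaving out single libraries gave 3 to 223 that fell and 0 to 39 that rose. The median PHO change inside domains was -1.15 with the input in the model and stayed below 0 in all 13 alternatives. The cause of these shifts was not tested, beyond the fewer regions tested in the smaller sets.

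The share of PH windows with H3K27me3 (in the order mel, sim, yak, pse) was 70.6%, 78.3%, 58.7% and 56.4% in 2 kb windows, 76.3%, 59.9%, 34.0% and 36.5% at a score of at least 4, and 39.1%, 20.3%, 21.0% and 10.7% in the 1000 windows highest over input. With no score minimum it was 83.7% in mel, 39.0% in sim, 35.9% in yak and 29.0% in pse. It was 54.8% in mel with scores at least 2 above input, 55.7% and 55.6% with mel replicates alone, and 31.7% and 35.5% with pse replicates alone. The share of PHO windows with PH was 56.4% in sim and 72.0% in yak in 2 kb windows. In sim it was 52.4% with scores at least 2 above input, 38.0% at a score of at least 4 and 38.1% with no score minimum. It was 41.7% there with no input filter, and 43.1% with PH replicates 1 and 2 as 2 samples. With PH replicate 3 alone the sim shares were 41.1% (PH windows with H3K27me3) and 62.8% (PHO windows with PH), against 68.1% and 38.9% with the near copies PH replicates 1 and 2 alone. Not run: TMM, library totals, DESeq2 and log2 CPM, which need counts; the pseudocount of the enrichment, since differences were used; comparisons between species at the same locus; and the gene lists. The unknown depth limits all of these.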

Other observations

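The tests of X dosage and of a swapped PC library were chosen only after the results were seen; the test of PHO enrichment outside PH peaks was written before its result.

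H3K27me3 formed long stretches in each of the 5 species at 4 to 12 h. Windows with a score of at least 4 and at least 1 above input were joined over gaps of up to 2 windows, a setting chosen after seeing the data. D. virilis, for which the other targets were not measured, had 792 stretches, 222 of them of at least 10 kb, and the longest measured 151 kb. D. melanogaster had 552 and 440 stretches in its 2 libraries, with longest ones of 89 and 63 kb. D. simulans had 516 with a longest of 322 kb, D. yakuba 511 with 193 kb, and D. pseudoobscura 499 and 565 with 194 kb in both libraries.

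Of the windows enriched for DSP1, 24.0% were enriched for PH, PC or H3K27me3 in D. melanogaster, 20.7% in D. simulans, 41.8% in D. yakuba and 25.4% in D. pseudoobscura. Windows enriched for none of PH, PC, H3K27me3 and H3K4me3 made up 60.9% of the DSP1 windows in D. melanogaster, 51.2% in D. simulans, 36.0% in D. yakuba and 55.4% in D. pseudoobscura. No share over all windows was computed for these classes, and PC alone covered 0.178%, 0.704%, 1.32% and 0.901% of all windows. PHO was enriched in 51.2%, 24.5%, 36.6% and 37.7% of DSP1 windows in the same order. It covered 0.882%, 0.549%, 0.802% and 1.02% of all windows, with odds ratios of 145, 91.9, 117 and 102. The replicates gave 45.6% and 53.3% in D. melanogaster and 38.8% and 36.1% in D. pseudoobscura, while the others had 1 DSP1 library. Among the 1000 windows highest over input, a setting under which D. melanogaster was lowest, the share with PHO was 19.9%, 21.2%, 28.7% and 28.0%. With no score minimum D. pseudoobscura had 68.4%.

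PHO scores at PH regions inside domains were lower in PHdel (median change -0.78). Fewer X chromosomes in the PHdel embryos as the whole cause is argued against by the autosomal regions inside domains, whose median change was -0.289 even in the library pair with the highest value. A lower yield of the PHdel PHO libraries at all PHO sites cannot be told apart from a loss at PH regions: 345 PHO windows outside PH peaks and domains, matched on their PHO score, changed by a share of 0.723 of the change at the regions, but by shares from -2.22 to 1.42 over the 4 library pairs. Those windows were picked from PHO at 4 to 12 h, which WT PHO replicate 2 resembles most (r = 0.827 over 1 kb windows). Whether this choice of windows makes the shares differ between the WT replicates was not tested. PHdel PHO replicate 2 was most alike to PHdel input replicate 2 (r = 0.891), and PHdel PHO replicate 1 to PHdel PHO replicate 2 (r = 0.810). A dependence of PHO on PH, the difference the design names, may account for the lower scores and stays open beside the lower yield.

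PH regions on X inside domains lay further below WT than autosomal ones (-1.25 against -0.67), and so did those outside domains (-0.62 against -0.01). Fewer X chromosomes per set of autosomes in the PHdel embryos, through a different sex ratio or a selection of embryos, may account for that excess. In windows without peaks or domains, the mean X minus autosome score of PHdel minus that of WT was -0.332, and the score was below both WT libraries of its kind in 5 of 6 PHdel libraries. The exception was PHdel input replicate 1, at -0.43 against -0.45 and -0.40 in the WT inputs; the test was first set on the inputs alone, where this library spoke against the explanation, and was widened to all 6 libraries after that value was seen (the PHdel inputs correlated with each other at r = 0.386 over 1 kb windows). PHdel input replicate 1 was closer to the inputs of 4 to 12 h (r = 0.718 and 0.771) than to the WT inputs of 16 to 18 h (0.506 and 0.425). For PHdel input replicate 2 the correlations with those WT inputs were 0.889 and 0.923. The exception thus rests on a library unlike the others of its age, which the fits with the input in the model also use. The explanation and a loss of PHO on X therefore cannot be told apart here.

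PC scores at PH regions inside domains were high in WT replicate 1 (median 4.84) and not in WT replicate 2 (2.39). A swapped genotype label of WT PC replicate 2 is argued against by the missing stretch of X, where this library scored 4.34 and the highest PHdel library 0.77. A weaker immunoprecipitation of that library and variation between embryo collections were not tested and stay open.

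At the PH region X 2015399 to 2020846, within the missing stretch of X, PC scored 1.64 and 1.15 in PHdel and 8.25 and 8.26 in WT, while input scored 0.36 and 0.02 in PHdel and 3.81 and 3.74 in WT. The mean score over all bins was 1.41 in both PHdel PC libraries. The region X 2028084 to 2037794 lies for the most part beyond the end of the stretch; its input scored 1.78 and 2.21 in PHdel and 3.93 and 3.52 in WT, and its PC 3.15 and 3.76 in PHdel and 8.60 and 6.64 in WT.

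Replicates varied in how alike they were. Of 29 replicate pairs, 1 was the near copy of D. simulans PH and was left out. Over the others the correlation across 1 kb windows ran from 0.168 to 0.986 with a median of 0.729, and 4 pairs lay under 0.5. These were PC (0.263) and PH (0.352) of D. melanogaster at 4 to 12 h, the PHdel inputs (0.386) and the D. yakuba inputs (0.168). In D. melanogaster the most similar library was a replicate of the same group for 10 of 26 libraries. D. yakuba PH replicate 2, whose antibody field reads input while its title reads PH, had a correlation of 0.836 with PH replicate 1, 0.860 with PC and at most 0.489 with an input; it was used as PH.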
